A study of Homo sapiens with 16 samples.

How the data were processed

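Ribosome profiling sequences the short mRNA fragments that translating ribosomes shield from nuclease (footprints). A library of fragmented total RNA from the same cells (input) gives the mRNA level, and the ratio of footprint to input is the translation efficiency (TE) of a gene. The series holds 16 libraries from 8 samples of A549, a human non-small cell lung cancer line, with 1 footprint and 1 input library per sample. Per the labels' protocols, cells were given fresh medium for 2 h and cycloheximide at 100 µg/mL for 5 min, which halts elongating ribosomes. Footprints were made with RNase I and selected at 30 nt, and input RNA was fragmented in 10 mM ZnCl2 and selected at 40 to 60 nt.

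The deposited values are TPM (reads per gene length, scaled to a fixed total in each library), which the authors gave in 3 tables of genes. The first table (sgM16) holds a control labelled untreated and 2 hybrid clones made with 1 guide against METTL16. The series text calls the control of this guide sgNS, while the sample label gives untreated and the column names hold the code WT. Label and column names thus point to cells without a guide, at odds with the series text. If so, guide delivery and cloning differ between control and clones along with METTL16 and cannot be told apart from it. The second table (shM16) holds 1 scrambled-hairpin control and 1 METTL16 knockdown. The third (sheIF4E2) holds another scrambled-hairpin control and 2 biological replicates of an eIF4E2 knockdown. Each table therefore has 1 control library per assay. Per the submitters' processing notes, reads were handled with cutadapt 2.8, Bowtie 1.3.0, Bowtie2 2.2.5, STAR 2.7.5c and featureCounts 2.0.1 on GRCh38. The gene lengths behind the TPM values are not given in the sources used here. Gene coordinates were taken from a RefSeq annotation of GRCh38.p14, which held 12445 of the 12587 symbols (98.9%).

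Each sample's column pair lists 9943 to 10750 genes, and the lowest input value listed was 1.00 TPM. The listed genes sum to 44.6% to 49.8% of each library's TPM total in the input libraries and to 16.1% to 35.1% in the footprint libraries. The tables were listed separately, and TPM was scaled within each library. Because TPM values of 1 library share a common step per gene, whole read counts could be recovered for 11892 of 11892 genes with at least 2 values, up to a factor common to a gene's libraries, at a relative tolerance of 1e-10. On simulated data with known steps the recovery was exact, up to that factor, for 2000 of 2000 genes. After noise with an SD of 0.0001 it gave 0, which the far smaller tolerance fixed in advance. The estimation of the steps themselves was not simulated. The recovered reads came to 196995 to 876336 per footprint library and 462611 to 699461 per input library. The median gene had 7 to 29 reads in a footprint library and 18 to 25 in an input library. Ratios of reads carry exact 95% Clopper-Pearson intervals, which cover counting error only.

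The test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1). A linear model of group means over both assays was fitted within each table of 6 libraries, with eBayes and an intensity trend. The TE contrast is the footprint change minus the input change. Tests were two-sided with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. Genes needed a mean of 1 TPM in both assays, which kept 8505 of 9056 genes in the sgM16 table, 8168 of 9706 in the shM16 table and 8597 of 9606 in the sheIF4E2 table. Both fitted tables had 2 residual degrees of freedom, all from the treated pairs, and the lone control was assumed to vary like them. Their p-values therefore measure spread between clones or replicates and not between independent controls. The shM16 table has no replicates and was given as values. A size rule counted genes whose TE differed from the control by at least 1 log2 unit in the same direction in every treated sample.

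A total of 32 gene lists, this model, the thresholds and the alternatives other than those named as added later were fixed before the data were examined. Lists with 5 or more measured members (29 lists) were tested against the other genes with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. In the shM16 table a list's median was placed among 10000 random lists of the same size and like expression. Genes were named by a fixed rule. METTL16 and EIF4E2 were always named, as was any member of the list of target and partner genes. For each contrast the rule took up to 10 genes per direction with the largest changes among those past the threshold with a mean of 10 TPM in both assays, filled to 5 by the largest changes of at least 1 log2 unit in both treated samples. For shM16 it took the 10 highest and 10 lowest TE changes, and for each list up to 4 members with the largest change.

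The call procedure was tested on simulated data with 200 changed genes, a dispersion of 0.05 and 20 sets, and on simulated libraries without any change. The alternatives were a pseudocount of 0.1, no filter, filters at 5 and 10 TPM, median-of-ratios scaling, quantile normalization, pooled spread, no trend, a replicate block, each assay alone, each replicate left out, both scramble libraries as controls, and a size of 1.5-fold. Scaling to the mitochondrially encoded mRNAs and limma's voom on the recovered reads were added later. Median-of-ratios and mitochondrial scaling apply 1 factor per library, so a list's median relative to all genes stays nearly unchanged under them by construction. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the other steps. Read positions, frames and fragment lengths are not in the deposited tables, so pausing, uORFs and codon occupancy were not analysed here. No genome sequence was used here, and GC content was not analysed here.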

Results

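METTL16 writes N6-methyladenosine (m6A) on RNA, with U6 snRNA and the MAT2A transcript as its textbook substrates, and eIF4E2 binds the mRNA cap and is known as a brake on initiation together with GIGYF1 and GIGYF2. The libraries ask how depletion of either goes with mRNA level, ribosome footprints and their ratio in A549 cells. Changes are log2 values of treated against the control of the same table, SE is the standard error of the model, and each fitted comparison sets 2 treated samples against 1 control.

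The targeted genes were measured in every library. METTL16 (chromosome 17, 2415715 to 2511888 in GRCh38.p14) stood at 12.8 TPM (45 reads) in the input of the untreated control and at 6.80 (28 reads) and 6.94 TPM (25 reads) in the sgM16 clones, made with a guide against METTL16. In footprints it stood at 8.04 TPM (32 reads) in the control and at 4.96 (41 reads) and 2.69 TPM (9 reads) in the clones. The METTL16 changes of -0.81 in input (SE 0.45, adjusted p = 0.551) and -0.95 in footprints (SE 0.45, adjusted p = 0.683) did not pass the test. By reads, the clones had 0.538 of the control's METTL16 input (interval 0.355 to 0.819) and 0.536 of its footprints (0.337 to 0.863). Clone 1 alone had a footprint ratio of 0.617 (0.379 to 1.01), an interval that includes no change. METTL16 mRNA and its footprints were still present in both clones, and protein levels were not used here. In the knockdown table, METTL16 input stood at 11.1 TPM (34 reads) in the scramble control and 3.50 TPM (19 reads) in shM16, and its footprints at 6.46 (37 reads) and 0.597 TPM (7 reads). The ratio was 0.315 in input (0.170 to 0.568) and 0.0923 in footprints (0.0347 to 0.210). These ratios include the general shift of this table: METTL16 changed by -1.43 in input and -2.22 in footprints, against all-gene medians of -0.325 and -1.06. Its TE change of -0.80 lay near the all-gene median of -0.76. In the sheIF4E2 table METTL16 input was 14.1 TPM in the control and 14.5 and 17.1 TPM in the knockdown samples.

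EIF4E2 (chromosome 2, 232550689 to 232583644) stood at 21.4 TPM (49 reads) in the input of its scramble control and at 7.69 (21 reads) and 3.57 TPM (10 reads) in the sheIF4E2 samples. Its footprints stood at 5.29 TPM (11 reads) in that control and at 3.27 (6 reads) and 1.3 TPM (3 reads) in the knockdown samples. The EIF4E2 input change of -1.83 (SE 0.60, adjusted p = 0.590) did not pass the test on TPM, while voom on the recovered reads gave -2.0 with an adjusted p of 0.00114. The ratio of reads was 0.262 in input (0.161 to 0.419) and 0.411 in footprints (0.150 to 1.09). By sample the footprint ratio was 0.617 (0.187 to 1.82) and 0.246 (0.0441 to 0.931), so only the second interval excludes 1. In the METTL16 clones the EIF4E2 values did not pass, at -0.28 in input (SE 0.38, adjusted p = 0.833) and -0.26 in footprints (SE 0.38, adjusted p = 0.853). In the METTL16 knockdown EIF4E2 input was 9.55 TPM against 8.47 TPM in its control, and footprints 2.79 against 3.33 TPM.

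**Figure D1:**
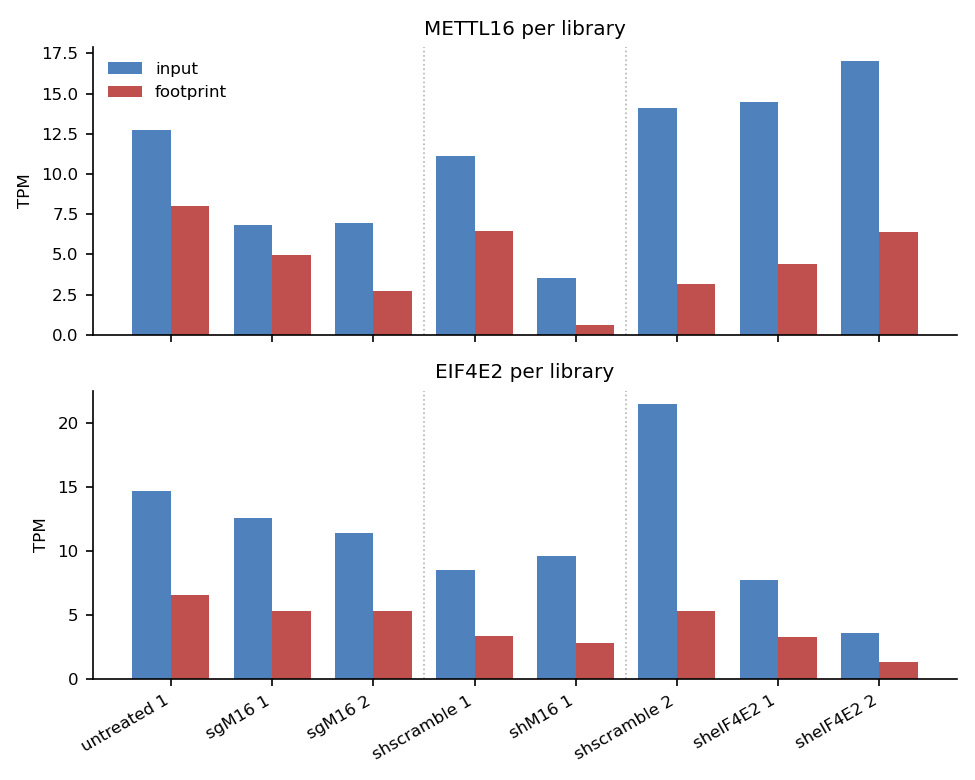
Bars give the TPM of METTL16 and EIF4E2 in each input and footprint library of the 3 tables. METTL16 input stood at 6.80 and 6.94 TPM in the sgM16 clones against 12.8 TPM in their control, and EIF4E2 input at 7.69 and 3.57 TPM in the sheIF4E2 samples against 21.4 TPM.

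The sgM16 clones against untreated cells. CYP1B1, a cytochrome P450 induced through the aryl hydrocarbon receptor, was the only mRNA called in the input: it rose by 2.85 (SE 0.30, adjusted p = 0.0469), from 21 reads in the control to 212 and 156 in the clones. The CYP1B1 call was lost with a pseudocount of 0.1 (adjusted p = 0.112), median-of-ratios scaling (0.0642), quantile normalization (0.0946), mitochondrial scaling (0.0570) and no trend (0.318). Simulated libraries without any change gave at least 1 higher call in 11 of 20 draws at a dispersion of 0.05, and in 5 of 20 at a dispersion of 0. Its input stood at 8.89 TPM in the untreated control, 76.8 and 64.7 TPM in the clones, and 148 and 67.0 TPM in the scramble libraries of the other tables, so the untreated library is the lowest of the controls for this gene, and its lone value decides the call. By reads its input ratio was 8.01 (interval 5.16 to 13.1), and its footprint ratio was 2.86 (2.07 to 4.04). SFN, the epithelial 14-3-3 sigma protein and a p53 target, had the same size of difference in both assays without passing: -1.64 in input (SE 0.26, adjusted p = 0.186) and -1.65 in footprints (SE 0.26, adjusted p = 0.379). ANPEP, a cell-surface aminopeptidase, had 43 footprint reads in the control and 270 and 156 in the clones (1.80, SE 0.31, adjusted p = 0.379). MAT2A, the methionine adenosyltransferase gene whose mRNA METTL16 methylates, had a footprint change of -0.77 (SE 0.37, adjusted p = 0.683) and an input change of -0.08, the mean of clones that differ in sign (-0.51 and 0.36).

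No gene's TE passed limma in the clones (0 higher, 0 lower), with 90 higher and 639 lower at an unadjusted p under 0.05 and a lowest adjusted p of 0.561. Voom called 0 and 0. Footprint levels also gave 0 and 0 calls, with 170 higher and 435 lower unadjusted, a lowest adjusted p of 0.0687, and 0 and 0 by voom. In simulated data the same fit found 21% of TE changes of 8-fold and 3.5% of those of 4-fold in this table. Of the TE values that met the naming rule without being calls, MT-ND6 had no footprint reads in the control, and the next highest were TRADD (2.31), an adaptor of the TNF receptor, and CFD (2.01). On the lower side were C15orf48 (-2.73), ATAD1 (-2.65) and IGFBP1 (-2.50). ATAD1 had 7 input reads in the control and 59 and 29 in the clones. Among partners of eIF4E2 and initiation, TE values were -1.50 for EIF3A (SE 0.50, adjusted p = 0.561), 1.02 for GIGYF1 and -0.93 for DDX6.

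TE was lower over most genes in both clones: the median over 8505 genes was -0.26 and -0.41, with 65.3% and 71.8% of genes below 0. Median-of-ratios scaling takes the median of the pair from -0.33 to -0.004, so list medians here are given relative to all genes. By the size rule 132 genes were higher and 783 lower in TE, and after the median was removed 274 were higher and 350 lower. Counting noise around the shift gave 74.8 higher and 286.3 lower on average in simulated libraries, which leave out variation between libraries. Both clones share 1 control, which raises the likeness of the pair: their TE changes correlated at r = 0.583 across genes against 0.529 in the simulation, and genes are not independent replicates.

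Antioxidant genes had the lowest p of the footprint lists in the clones. NRF2 targets, the antioxidant genes that KEAP1-mutant A549 cells express highly, fell in footprints relative to other genes: 25 of 29 measured members were lower in both clones and 0 were higher. Their relative median was -0.32 (camera adjusted p = 1.23e-06, adjusted p = 0.773 with an estimated correlation). Adjusted over the list alone 6 members were lower, against 0 over all genes, and AKR1C2 (-1.24, SE 0.28), ME1 (-1.11, SE 0.29) and SRXN1 (-1.31, SE 0.37) were among the largest values. The same list was lower in input, with 18 of 29 members below the control in both clones and 5 above (relative median -0.33, adjusted p = 0.0125, and 0.897 with an estimated correlation), a call lost with quantile normalization (0.175, relative median -0.12), while the footprint call held under each scaling. Interferon response genes rose in footprints relative to other genes. Of 10 measured members 4 were higher in both clones and 0 lower (relative median 0.42, adjusted p = 0.00148, adjusted p = 0.773 with an estimated correlation), led by IFI6 (1.49, SE 0.49) and IFI35 (1.25), a call that held under each scaling. Adjusted over the list alone 0 interferon genes passed, as over all genes.

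Replication-dependent histone mRNAs, which lack a poly(A) tail and are made in S phase, fell in the clones' input: 24 of 31 were lower in both clones and 0 higher (relative median -0.49, adjusted p = 1.46e-07, adjusted p = 0.897 with an estimated correlation). Quantile normalization kept this call at a smaller relative median of -0.23 (adjusted p = 1.05e-04). The 13 mRNAs encoded by mitochondrial DNA were all higher in input in both clones (relative median 0.39, adjusted p = 0.00209, and 0.897 with an estimated correlation), which scaling to these same mRNAs took to 0.0745 (relative median 0.35). In footprints 9 of the 13 were higher and 2 lower, 1 passing adjusted over the list alone (relative median 0.47, adjusted p = 5.39e-05, adjusted p = 0.773 with an estimated correlation). MT-ND6 had 0 footprint reads in the control and 6 and 5 in the clones, and with the control set to a floor of 3 reads the list's median stayed at 0.24 while its mean was 0.21 in place of 0.50. Lung epithelial markers fell in input, with 6 of 9 lower and 2 higher (relative median -0.87, adjusted p = 0.0125, adjusted p = 0.897 with an estimated correlation), from KRT19 (-1.50) to CAV1 (0.96). Immediate early genes also fell in input, with 12 of 20 lower and 3 higher (relative median -0.42, adjusted p = 0.0144, and 0.897 with an estimated correlation). Both of these calls were lost with quantile normalization (adjusted p = 0.0534 for each, relative medians -0.68 and -0.29).

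Other calls in the clones were lost under some of the scalings. Chaperones, the only list called in TE, had 19 of 24 members lower in both clones and 0 higher (relative median -0.34, adjusted p = 0.0228, adjusted p = 0.905 with an estimated correlation), with HSP90AA1 at -1.72 (SE 0.35) and HSPA4 at -1.33. The chaperone TE call was lost with median-of-ratios (0.157) and mitochondrial scaling (0.153) and kept with quantile normalization (0.00563). The relative medians of -0.31 and -0.33 under the scalings that lost it are nearly fixed by construction. In footprints, cytosolic ribosomal proteins were called lower (62 of 77 lower, 1 higher, relative median -0.14, adjusted p = 5.39e-05, and 0.773 with an estimated correlation), as were oxidative phosphorylation genes (46 of 58, 0.00246), chaperones (23 of 24, 0.00739), histones (22 of 31, 0.00739) and initiation factors (30 of 40, 0.0297). Of all genes 68.2% and 66.3% were lower in footprints of each clone taken alone. The list counts need a member to be lower in both clones, and the share of all genes lower in both is not given here. With an estimated correlation the last 4 lists had an adjusted p = 0.773. After median-of-ratios scaling the adjusted p was 0.0351 for ribosomal proteins, 0.0659 for oxidative phosphorylation, 0.0946 for chaperones, 0.0931 for histones and 0.148 for initiation factors, and quantile normalization took ribosomal proteins to 0.0675. The relative medians of these 5 lists, in the same order, went from -0.14, -0.13, -0.08, -0.09 and -0.15 to -0.12, -0.10, -0.06, -0.07 and -0.13 with median-of-ratios scaling. The m6A machinery had 13 of 18 members lower in TE in both clones and 0 higher without a call (adjusted p = 0.251). The lists without a call had adjusted p from 0.0634 to 0.790 in TE, 0.0524 to 0.977 in footprints and 0.0610 to 0.955 in input.

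METTL16 knockdown against its scramble control, 1 library of each kind and so without a test. Footprint TPM was lower for 95.2% of 8168 genes (median -1.06), and TE was lower for 84.3% (median -0.76), while the input median was -0.33. Median-of-ratios scaling takes the TE median to -0.002. With both scramble libraries as controls it is -0.43 and genes lower in TE by size number 1355 in place of 2937. MAT2A had changes of -0.83 in input and -1.74 in footprints. Of 15 measured target and partner genes 14 had lower TE, among them ZNF598 (-2.32), a sensor of collided ribosomes, GIGYF1 (-2.12) and GIGYF2 (-1.64). Their TE median lay at percentile 4.29 of random lists, and their footprint median of -1.49 at percentile 0.40.

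The highest TE value by the naming rule in the knockdown was GNG5 (2.46), a G-protein gamma subunit, with 3 control and 24 knockdown footprint reads (ratio 3.90, interval 1.19 to 20.3). UTP3 (1.60), DUSP23 (1.3) and EMC6 (1.25) followed. The lowest values were SURF2 (-3.50), with 24 control footprint reads and 1 in the knockdown (ratio 0.0203, 0.000494 to 0.125), SRPX (-3.11), PDIA5 (-3.09) and AGRN (-2.87). AGRN, the basement-membrane proteoglycan agrin, had 200 and 73 footprint reads (ratio 0.178, 0.134 to 0.234) and 82 and 222 input reads (ratio 1.53, 1.18 to 1.99). CDT1, the replication licensing factor, had 38 and 11 footprint reads (ratio 0.141, 0.0651 to 0.282). By the size rule 164 genes were higher and 2937 lower in TE, and 808 and 576 after the median was removed. In footprints these counts were 28 and 4442, and 487 and 278 after the median was removed, so the balance turns with the general shift. Simulated counting noise around the shift, without variation between libraries, gave 66.3 and 2273.2 in TE.

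Percentiles here rank random gene lists within 1 pair of samples and do not measure variation between libraries. Mitochondrially encoded mRNAs stood apart in the METTL16 knockdown, with 10 of 13 higher in TE (median 0.19, percentile 100) and 13 of 13 higher in footprints (median 0.41). Their summed footprint TPM was 53975 in the control and 69046 in the knockdown, but 10707 in the other scramble control. In input the sums were 190868, 211308 and 79641, so the controls differed more than the knockdown did from its own. Oxidative phosphorylation genes encoded in the nucleus had a TE median of -0.64 (percentile 99.74), and NRF2 targets of -1.09 (percentile 0.87), with 29 of 30 lower. Histone mRNAs were lower for 31 of 31 members in input (median -0.85, percentile 0.00) and in footprints (median -1.49, percentile 0.17). G2/M genes had a footprint median of -1.44 (percentile 0.21), and cholesterol synthesis genes one of -0.74 (percentile 99.96). In input, mitochondrial ribosomal proteins lay at percentile 0.01 and epithelial-mesenchymal genes at 99.97, with VIM at -2.19 and LAMB3 at 1.69. Interferon genes had an input median of 0.19 and a mean of -0.17, which differ in sign.

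**Figure D2:**
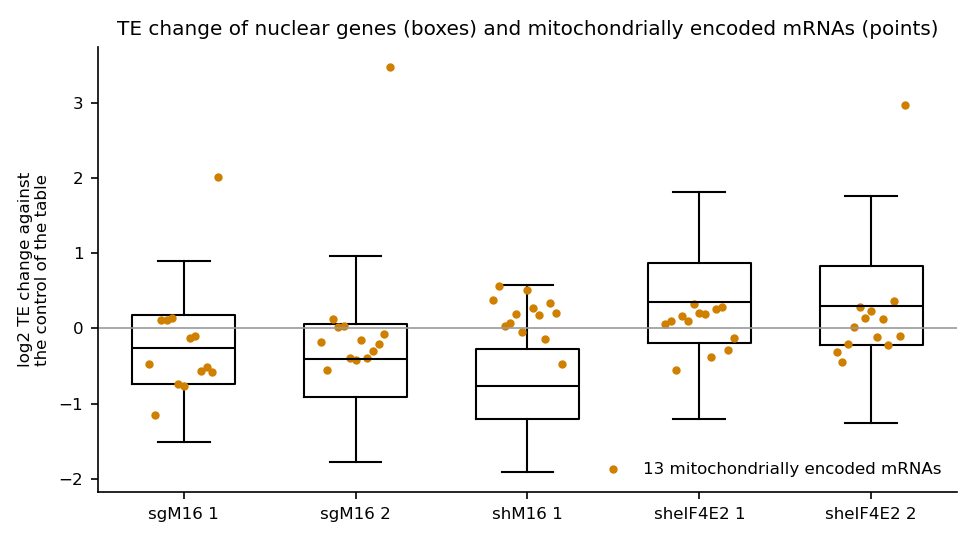
Log2 TE change of each treated sample against the control of its table, with boxes from the lower to the upper quartile of nuclear genes, whiskers from the 5th to the 95th percentile, and points for the 13 mitochondrially encoded mRNAs. The all-gene medians are -0.26 and -0.41 in the METTL16 clones, -0.76 in the knockdown and 0.35 and 0.31 in the sheIF4E2 samples, and median-of-ratios scaling takes each table's median to within 0.02 of 0.

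EIF4E2 knockdown against its scramble control. LBH, a developmental transcription cofactor, rose in both assays: by 2.94 in footprints (SE 0.20, adjusted p = 0.0102), from 19 reads to 148 and 160, and by 2.59 in input (SE 0.20, adjusted p = 0.0247), from 169 reads to 1261 and 1219. SPARC, a secreted glycoprotein of the extracellular matrix, rose by 3.61 in footprints (SE 0.39, adjusted p = 0.0311), from 3 reads to 61 and 45 (ratio 17.7, interval 5.90 to 87.3), and had 14, 95 and 109 input reads. IDH2, the mitochondrial isocitrate dehydrogenase, rose by 3.18 (SE 0.33, adjusted p = 0.0311), from 2 reads to 25 and 25 (ratio 12.5, 3.30 to 106), and IGFBP7, a secreted binding protein of insulin-like growth factors, by 2.78 (SE 0.32, adjusted p = 0.0311), from 3 reads to 18 and 32 (ratio 8.36, 2.7 to 41.9). CEBPD, a transcription factor of the acute-phase response, rose from 1 footprint read to 7 and 11 (ratio 9.03, 1.43 to 376), with 22 input reads in the control and 28 and 31 in the knockdown.

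In all, limma called 49 genes higher and 5 lower in footprints, against 17 and 5 with median-of-ratios scaling, 20 and 8 with quantile normalization, 27 and 4 with voom, and 0 and 0 without a trend or with each assay fitted alone. With both scramble libraries as controls 5 and 3 were called, 3 of them shared with the 54. Without replicate 1, in the fit pooled over tables, 9 and 2 were called, and without replicate 2, 48 and 9, where the same pooled fit with both replicates called 120 and 12. In simulated data with changed genes 36.3% of footprint calls in this table were false. In simulated libraries without change the fit called 7.5 genes higher on average and at most 19 at a dispersion of 0.05. At a dispersion of 0 it called 2.1 on average and at most 7. Of the 49, 12 had 0 footprint reads in the control, 11 had 1 to 3, and 26 had more. Genes at 0 control reads include CNFN (2 and 5 reads in the knockdown), EDN2 (8 and 8), FHL3 (12 and 7) and HBQ1 (3 and 2). The lower end of the counting interval of the ratio was 0.723 for CNFN and 0.460 for HBQ1, which does not exclude 1, and 1.94 for EDN2 and 2.34 for FHL3. The input change was at least 1 for 15 of the 49. The 5 genes called lower, named after their values were seen, had 0 reads in both knockdown libraries: STEAP1 (11 control reads), ASPHD1 (6), BCL2A1 (5), C19orf71 (4) and H4C12 (1). CXCL5, a neutrophil chemokine, did not pass in footprints (-1.50, SE 0.26, adjusted p = 0.0682) or in input (-2.33, SE 0.26, adjusted p = 0.102), with 298 input reads in the control and 72 and 70 in the knockdown, while voom gave its input an adjusted p of 9.58e-14. CYP1B1 input, with 140 control reads and 40 and 32 in the knockdown (ratio 0.213, 0.158 to 0.285), had an adjusted p of 0.303. AGR2, a disulfide isomerase of secretory cells, had a footprint change of -1.70 (SE 0.45, adjusted p = 0.138).

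**Figure D3:**
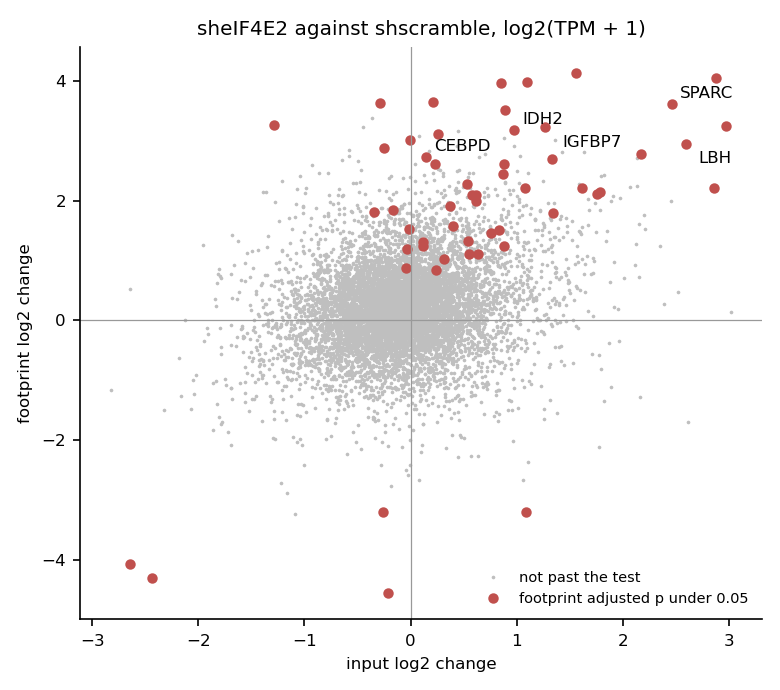
Log2 change in footprints against log2 change in input of each gene in the sheIF4E2 table, with genes called in footprints in red and the others in grey. LBH lies at 2.59 in input and 2.94 in footprints, and 49 genes are called higher and 5 lower, or 17 and 5 after median-of-ratios scaling.

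LBH was the only gene called in input (1 higher, 0 lower, with 266 and 355 unadjusted), where voom called 68 higher and 199 lower. The LBH input call was lost with a pseudocount of 0.1 (adjusted p = 0.0965) and no trend (0.602), its footprint call was lost with no trend (0.132), and without either replicate the fit pooled over tables gave 0 higher input calls. No gene's TE passed limma in this table (0 higher, 0 lower), with 688 and 119 at an unadjusted p under 0.05, a lowest adjusted p of 0.475, and 1 and 0 by voom. In simulated data the fit found 13.9% of TE changes of 8-fold and 2% of those of 4-fold. Values that met the naming rule without being calls include CHCHD5 (3.12), SPC25 (3.02) and PIR (2.72) on the higher side and CADM4 (-2.88), ANKRD1 (-2.04) and FADD (-1.73) on the lower. Among partners, EIF4ENIF1, which shuttles cap-binding proteins to the nucleus, had a TE value of 1.92 (SE 0.68, adjusted p = 0.503), EIF3A one of 1.53 (SE 0.41, adjusted p = 0.475) and GIGYF1 one of -0.96. The median TE change over 8597 genes was 0.35 and 0.31 in the samples, with 32.2% and 34.4% of genes below 0, and median-of-ratios scaling takes the pair's median from 0.32 to 0.02. With both scramble libraries as controls the median is also 0.02 and genes higher by size number 375, and the scrambles lie 0.60 apart in median TE, so the size of the shift depends on the scramble used. By the size rule 867 genes were higher and 215 lower in TE, and 423 and 415 after the median was removed, where counting noise around the shift gave 519.5 and 116.6. That noise leaves out variation between libraries. Between the scramble controls, 1 sample against 1, TE was at least 1 higher in the shM16 table's control for 2882 genes. It was at least 1 lower there for 566.

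Histones were the list with the lowest p in footprints and TE of this knockdown. Their footprints rose as a list, with 30 of 31 measured members higher in both samples and 0 lower (relative median 0.49, adjusted p = 2.76e-16, adjusted p = 0.641 with an estimated correlation), and 25 members passed adjusted over the list alone against 5 over all genes. H4C12, a histone gene outside the list, was called lower on 1 control read and 0 in the knockdown. H2BC17 rose by 1.3 (adjusted p = 0.0311), H2AC13 by 1.19 (0.0412) and H4C4 by 1.11 (0.0424). Histone TE was also higher for 26 of 31 and lower for 0 (relative median 0.27, adjusted p = 1.05e-07, adjusted p = 0.787 with an estimated correlation), with 4 members past the threshold adjusted over the list alone and 0 over all genes. Their input was higher for 21 and lower for 4 (relative median 0.28, adjusted p = 4.17e-05, adjusted p = 0.632 with an estimated correlation). These 3 calls held under each scaling, with the relative median in TE at 0.15 under quantile normalization. No list was tested with both scramble libraries as controls, so the dependence of list calls on the lone control was not tested.

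Amino-acid response genes fell in the same cells. ATF4 targets, which the integrated stress response induces, were lower in input for 17 of 21 members and higher for 2 (relative median -0.45, adjusted p = 3.07e-06, adjusted p = 0.632 with an estimated correlation), with 6 lower adjusted over the list alone and 0 over all genes. GDF15 (-1.94, SE 0.43), CHAC1 (-1.70, SE 0.44), STC2 (-1.32) and PCK2 (-1.21) had the largest values. Their footprints were lower for 11 and higher for 5 (relative median -0.40, adjusted p = 0.00177, adjusted p = 0.814 with an estimated correlation). Aminoacyl-tRNA synthetases, many of them ATF4 targets, were lower in input for 18 of 22 and higher for 1 (relative median -0.37, adjusted p = 4.17e-04, and 0.632 with an estimated correlation), with EPRS1 at -1.74 (SE 0.36). Synthetase footprints were lower for 11 and higher for 5 (adjusted p = 0.0223, and 0.814 with an estimated correlation). The unfolded protein response was lower in input for 19 of 23 and higher for 2 (relative median -0.26, adjusted p = 0.00365, adjusted p = 0.632 with an estimated correlation), led by DNAJB9 (-2.12, SE 0.58). All 5 calls held under each scaling.

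Mitochondrially encoded mRNAs fell in this knockdown, in footprints for 9 of 13 with 0 higher (relative median -0.51, adjusted p = 2.04e-04, and 0.641 with an estimated correlation) and in input for 11 of 13 with 0 higher (relative median -0.25, adjusted p = 4.17e-04, and 0.632 with an estimated correlation). Adjusted over the list alone, 2 were lower in footprints and 3 in input, against 0 over all genes. The input call was lost with quantile normalization (0.102), where the relative median was -0.01, and with mitochondrial scaling (0.374), where its -0.22 is nearly fixed by construction. MT-ND6 had 0 control footprint reads, and with a floor of 3 there the relative footprint median was -0.53. Calls for ribosomal proteins and chaperones depended on the scaling. Ribosomal protein TE was higher for 63 of 78 members and lower for 4 (relative median 0.08, adjusted p = 6.49e-04, adjusted p = 0.787 with an estimated correlation). The adjusted p was 0.715 after median-of-ratios scaling (relative median 0.04), 0.503 with quantile normalization and 0.00312 with mitochondrial scaling. Ribosomal protein footprints were higher for 54 and lower for 8 (adjusted p = 0.0200, adjusted p = 0.814 with an estimated correlation), 0.676 after median-of-ratios scaling, 0.974 under quantile normalization and 9.52e-06 with mitochondrial scaling, and RPS27 rose by 1.24 (adjusted p = 0.0468). Chaperone TE was higher for 20 of 24 and lower for 2 (relative median 0.22, adjusted p = 0.00961, adjusted p = 0.787 with an estimated correlation). The adjusted p was 0.521 after median-of-ratios scaling (relative median 0.17), 0.407 with quantile normalization and 0.0178 with mitochondrial scaling. Smaller calls were lower mRNA decay factors in footprints (12 of 26 lower, 6 higher, adjusted p = 0.0459, and 0.814 with an estimated correlation), with DCP1B at -1.65, and in input lower elongation factors (9 of 12, 0.0196), NRF2 targets (22 of 30, 0.0304) and chaperones (18 of 24, 0.0348), each with an adjusted p of 0.785 with an estimated correlation. Each of these 4 was lost under at least 1 scaling. Where lost with median-of-ratios scaling, their relative medians, nearly fixed by construction, were -0.475 for decay factors, -0.043 for NRF2 targets and -0.159 for chaperones. For elongation factors the value was -0.165 where lost with mitochondrial scaling. The lists without a call had adjusted p from 0.0886 to 0.955 in TE, 0.133 to 0.988 in footprints and 0.0748 to 0.968 in input. Fry's directional test called 0 lists in any contrast of either table, with a lowest adjusted p of 0.0743. Its mixed test, which counts changes in either direction, called 1, 0 and 5 lists in TE, footprints and input of the clones and 1, 10 and 8 in sheIF4E2.

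**Figure D4:**
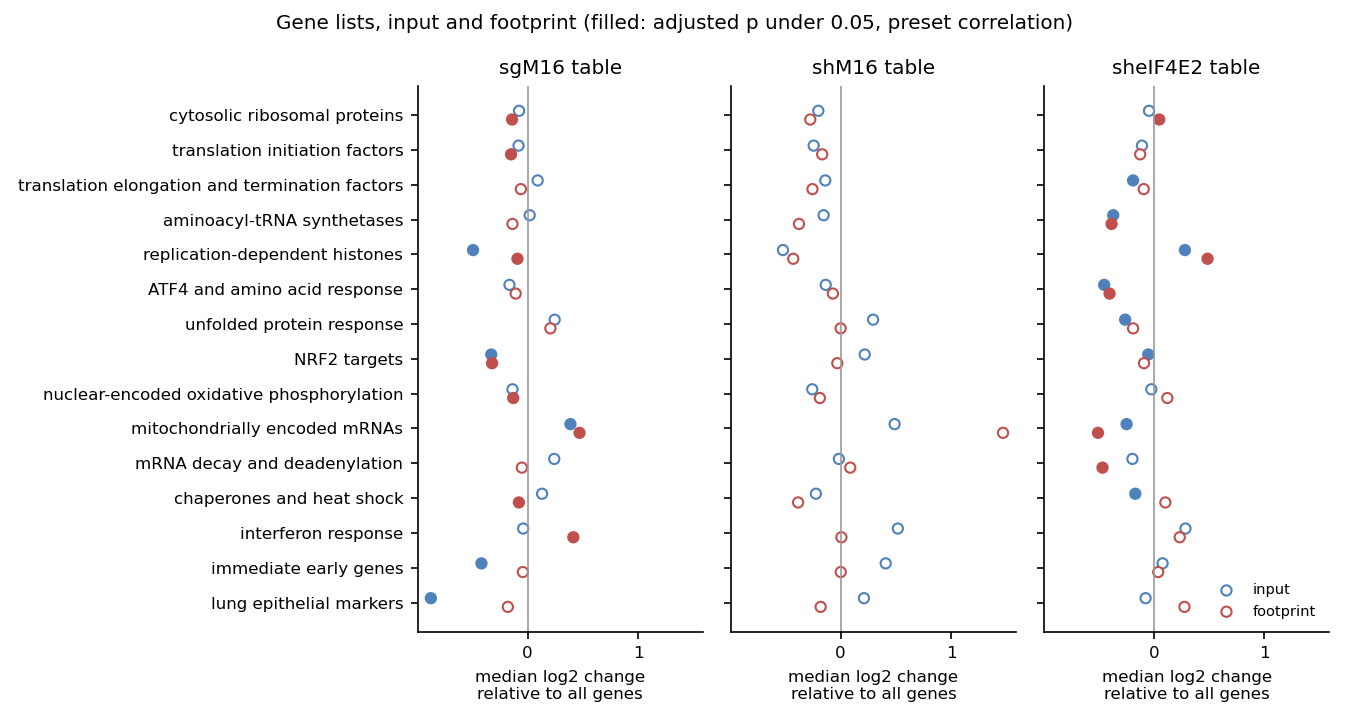
Median log2 change relative to all genes in the footprint and input contrasts of the 3 tables, for the gene lists called in any fitted contrast. Filled points mark an adjusted p under 0.05 at the preset correlation and open points the others (the shM16 table was not tested). Histones stand at 0.49 in sheIF4E2 footprints and NRF2 targets at -0.32 in the footprints of the METTL16 clones, and ribosomal protein footprints in sheIF4E2 at 0.05, a call lost under quantile normalization.

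METTL16 and eIF4E2 depletion side by side. The difference between the TE effects of the METTL16 clones and the sheIF4E2 samples passed for 0 genes higher and 0 lower of 7949 in limma (97 and 1110 at an unadjusted p under 0.05, lowest adjusted p = 0.193, and 0 and 1 by voom), with a median of -0.67. Chaperones (median difference -1.13, adjusted p = 0.00114), ribosomal proteins (-0.73, 0.00114) and G2/M genes (-1.20, 0.0194) differed at the preset correlation, with an adjusted p of 0.985 for each with an estimated correlation. Relative to all genes their medians were -0.47, -0.06 and -0.53. After median-of-ratios scaling these were -0.39, 0.01 and -0.54 with adjusted p of 0.146, 0.905 and 0.257. Such scaling moves relative medians little by construction, and that of ribosomal proteins, near 0, changed sign. Quantile normalization gave 0.00540, 0.0246 and 0.0613 and mitochondrial scaling 0.0451, 0.241 and 0.0877, so chaperones passed under both. Mitochondrially encoded mRNAs, not called at first (relative median 0.49, adjusted p = 0.887), passed on the higher side with quantile normalization alone (0.64, adjusted p = 8.10e-04). Across genes, which are not independent replicates, the TE changes correlated at r = -0.135 between METTL16 clones and sheIF4E2 (Spearman -0.15), -0.043 between clones and METTL16 knockdown (-0.048), and 0.019 between METTL16 knockdown and sheIF4E2 (0.022). Of genes past the size rule, 229 were lower in both METTL16 tables, where independent lists share 248.7. A further 96 were lower in the clones and higher in sheIF4E2, against 72.1, and 12 the reverse, against 2.5. Higher in both were 15, against 11.6, and lower in both 11, against 15.7. The METTL16 knockdown did not repeat the first excess: 243 genes were lower there and higher in sheIF4E2, against 268.2, and 9 the reverse, against 3. Higher in this knockdown and in sheIF4E2 were 21, against 13.9, and lower in both 62, against 57.6. The numbers for independent lists take every gene as equally likely to pass the rule. The controls themselves differ: TE had a median difference of 0.60 between the scramble libraries, 1.07 between the untreated control and the scramble of the sheIF4E2 table, and 0.42 between the untreated control and the other scramble. The tables were listed separately, but TPM is scaled within each library, so these differences are formed in the same way as those within a table.

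Few markers of other cell types were among the genes kept in any table, which by itself does not show a low level. Of 15 fibroblast markers 4 were measured in each table, of 11 endothelial markers 1 (ESAM), and of 15 leukocyte markers 1 (CD14) in each METTL16 table and 0 in the sheIF4E2 table.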

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

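Tests on dilution by other RNA and on the mRNA level of the higher genes were chosen only after the results were seen, while those on depth, on the lone controls and on few reads were set earlier. Results here were picked because groups differed or moved in opposite directions.

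The median TE change over all genes was -0.26 and -0.41 in the METTL16 clones and 0.35 and 0.305 in the sheIF4E2 samples, every sample of a group on the same side of its own control. This difference of medians was not tested, and with both scramble libraries as controls the sheIF4E2 median was 0.020, so its size depends on the scramble used. Unequal depth is argued against: with reads thinned to equal depth the smallest ratio of thinned to full median over the 3 tables was 0.99. If RNA outside the tables had diluted every listed gene alike, nuclear and mitochondrially encoded mRNAs would have shifted together. Their medians differed by -0.95 in the METTL16 knockdown (SE 0.077 over 13 mRNAs) and by 0.28 in sheIF4E2 (SE 0.122). These SEs are over mRNAs of the same libraries and not over libraries. Nuclear TPM per mitochondrially encoded TPM in footprints was 4.11 and 15.4 in the scramble libraries, so the mitochondrial share itself varies between controls. The gaps therefore cannot decide on dilution in these tables. The share of the footprint TPM total held by the listed genes moved the same way as the median TE change in every treated sample. It was below the control in both clones and in the METTL16 knockdown, and above it in both sheIF4E2 samples. The input share moved proportionally less in each. Dilution would give this, but so would a general change in footprints of the listed genes, so the shares cannot tell these apart. In the clones the gap of -0.006 (SE 0.247) leaves dilution open, since 13 mRNAs spread too widely, and a change of translation by METTL16 or eIF4E2 depletion stays open too, as does the lone control of each table, which differs from the other controls by up to 1.07 in median TE.

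The 783 genes with lower TE in both clones are the next pattern. Their relative median was -1.20 against the untreated control, -0.34 against the scramble of the sheIF4E2 table (775 genes) and 0.18 against the scramble of the shM16 table (763 genes), so a candidate explanation is the lone untreated library, which cannot be told apart from an effect of METTL16 depletion because the scramble cells went through another treatment and table. Few reads may also add to it: 5.71% of the genes in the third with the most reads passed the rule, against 10.1% and 11.8% in the others. An effect of METTL16 depletion was not tested apart from these.

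The 49 genes with higher footprints in sheIF4E2 had a relative median of 2.01 against their own scramble library and 0.46 against the other scramble (48 genes), as would follow if chance or library values of the lone control footprint library made most of the pattern, since these genes were chosen with that library. Of the 49, 23 had 3 or fewer reads there, against 20.5% of all genes. Their relative input change of 0.72 leaves a higher mRNA level open as part of the cause. An effect of eIF4E2 depletion on the rest was not tested apart from these.

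Lists whose TE effect differed between the METTL16 clones and sheIF4E2 were ribosomal proteins (median difference -0.725), chaperones (-1.13) and G2/M genes (-1.20), each tested with camera at a preset correlation and not past the threshold with an estimated correlation (adjusted p = 0.985). The median difference over all genes was -0.669, and relative to it these were -0.056, -0.465 and -0.528. With median-of-ratios scaling the relative values were 0.014, -0.388 and -0.539, and none of these lists passed. The clones and the METTL16 knockdown moved apart in mitochondrially encoded mRNAs, with median TE changes of -0.48 and -0.18 in the clones and 0.19 in the knockdown, and in interferon genes, with 0.11 and 0.01 against -1.14. Relative to all genes of each sample the mitochondrial values were -0.22, 0.23 and 0.95, so the second clone lay on the side of the knockdown, and the interferon values were 0.36, 0.42 and -0.37. These last differences were not tested.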

How the results depend on the processing

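Mitochondrial scaling, voom, scaled list tests, and the alternatives for named genes and, other than median-of-ratios scaling, for each table's median TE change were chosen after seeing the data. Over all counts, medians and correlations 164 alternative values stayed within the spread or within 1.5 times the count and 124 moved. For named genes 704 kept their direction and side of the threshold, 38 lost it and 25 gained it. Only values past the threshold in the report could lose it, and most named values were not. Values that failed again count among the 704, so the 38 are not a share of all values. The number of checks on called values alone is not given here. A further 5 values, none of them past the threshold in the report, changed sign, and no called value did. Where a count moved the cause was not tested, unless the alternative itself shows it. The calls rest on 2 treated samples against 1 control library, and the shallowest control footprint library (sheIF4E2 table, 196995 reads, median 7 per gene) limits what its folds can show. Footprint and input deviations of the same sample correlated at 0.147 across genes in the clones and at -0.016 in sheIF4E2, so pairing had little to remove, and with a replicate block TE calls stayed at 0 higher and 0 lower in both tables and for their difference, with 1 and 3 lists.

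For reference, the values in the report are, as higher and lower, 0 and 0 (clone TE and footprints), 1 and 0 (clone input), 0 and 0 (sheIF4E2 TE), 49 and 5 (sheIF4E2 footprints) and 1 and 0 (sheIF4E2 input). By size they are 132 and 783 in the clones, 164 and 2937 in the METTL16 knockdown and 867 and 215 in sheIF4E2. The median TE changes are -0.33, -0.76 and 0.32.

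With a pseudocount of 0.1, clone footprints gave 3 higher calls and clone input 0, sheIF4E2 footprints 155 and 10 (all 54 of the reported calls among them) and sheIF4E2 input 0 higher. The size rule gave 217 higher in the clones, the medians were -0.94 in the METTL16 knockdown and 0.36 in sheIF4E2, 2 lists were called in clone TE in place of 1, and r between clones and sheIF4E2 was -0.083 in place of -0.135. Without a filter, sheIF4E2 footprints gave 10 and 3 calls, 13 shared with the 54. At 5 TPM, which tests fewer genes, clone footprints gave 1 higher call, sheIF4E2 footprints 3 lower and sheIF4E2 input 2 and 1. The size rule gave 40 and 449 in the clones, 38 and 1751 in the METTL16 knockdown and 425 and 62 in sheIF4E2, with medians of -0.88 and 0.36 in the last pair. At 10 TPM, r between clones and sheIF4E2 was -0.213.

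Median-of-ratios scaling, which by construction removes a general shift, gave 0 higher calls in clone input and 17 in sheIF4E2 footprints (22 shared with the 54 in both directions). By size it gave 257 and 372 in the clones, 689 and 697 in the METTL16 knockdown and 484 and 378 in sheIF4E2, with medians of -0.004, -0.002 and 0.019, and 4 lists in clone footprints in place of 8. Quantile normalization gave 0 higher in clone input, 20 and 8 in sheIF4E2 footprints (25 shared), and 2, 3 and 3 lists in clone TE, footprints and input in place of 1, 8 and 5. Mitochondrial scaling gave 1 higher in clone footprints, 0 in clone input, 120 in sheIF4E2 footprints (54 shared) and 2 in sheIF4E2 input. By size it gave 242 and 483 in the clones, with medians of -0.105, -0.916 and 0.194 in the 3 tables, 0 lists in clone TE and 4 in sheIF4E2 input in place of 8.

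Pooling the spread over tables gave 120 and 12 sheIF4E2 footprint calls (38 shared). Without a trend clone input gave 0 higher, sheIF4E2 footprints 0 and 0 (0 shared) and sheIF4E2 input 0 higher. With each assay alone, clone footprints gave 6 and 4, sheIF4E2 footprints 0 and 0 and sheIF4E2 input 220 and 210. Voom gave 1 lower in clone input, 1 higher in sheIF4E2 TE, 27 higher in sheIF4E2 footprints (13 shared in both directions), 68 and 199 in sheIF4E2 input, and 1 lower for the difference of TE effects. Voom with pooled spread gave 1 lower in clone TE, 1 and 5 in clone footprints, 36 and 12 in clone input, 2 and 0 in sheIF4E2 footprints (2 shared) and 15 and 57 in sheIF4E2 input. With both scramble libraries as controls, sheIF4E2 footprints gave 5 and 3 (3 shared), the size rule 1355 lower in the METTL16 knockdown and 375 higher in sheIF4E2, and the medians were -0.435 and 0.020. A planned pooled test of the METTL16 knockdown was run and is not used, since its treated arm holds 1 library.

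A smaller size of 1.5-fold, which admits more genes, gave 343 and 1887 in the clones, 401 and 4932 in the METTL16 knockdown and 1904 and 498 in sheIF4E2. With an estimated correlation, and with fry's directional test, 0 lists were called in each of the 6 contrasts, where the preset correlation gave 1, 8 and 5 in the clones and 3, 6 and 8 in sheIF4E2.

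Leaving out each replicate used the pooled fit and assumes that the lone sample varies like the others. It gave 0 to 1 lower in clone footprints, 0 to 0 higher and 0 to 1 lower in clone input, 9 (without sheIF4E2 replicate 1) to 48 higher and 2 to 9 lower in sheIF4E2 footprints (6 and 17 shared with the 54), 0 to 0 higher in sheIF4E2 input, and 0 to 1 higher for the difference. By size, 1 sample admits more genes than a pair: 353 to 403 and 1315 to 1822 in the clones, and 1659 to 1758 and 585 to 666 in sheIF4E2. The r between clones and sheIF4E2 ran from -0.153 to -0.083.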

Other observations

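Receptor tyrosine kinases and their ligands drive many lung cancers. In sheIF4E2 input, MET had a value of -1.13 (SE 0.30, adjusted p = 0.512), FGFR4 of 1.00 (SE 0.29, adjusted p = 0.524) and EREG of -1.03 (SE 0.28, adjusted p = 0.517), and in the METTL16 clones FGFR4 input had -1.75 (SE 0.37, adjusted p = 0.223). HIF1A, the oxygen-regulated transcription factor, had 1.53 in the clones' input (SE 0.27, adjusted p = 0.186) and -1.53 in their TE (SE 0.38, adjusted p = 0.561). Of the m6A readers, YTHDF3 had a TE value of -1.22 in the clones (SE 0.48, adjusted p = 0.561) and of 1.47 in sheIF4E2 (SE 0.50, adjusted p = 0.502). ALKBH5, an m6A eraser, had 1.25 in sheIF4E2 footprints (SE 0.25, adjusted p = 0.0950).

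Some genes were listed in the samples of 1 group alone, and so were outside every comparison. The lowest input value listed was 1.00 TPM, but why a gene was not listed was not tested. CPLX2, a synaptic complexin, was listed at 66.7 TPM in the untreated control and in neither METTL16 clone, and EDEM3, of glycoprotein quality control, at 8.91 TPM or more in both clones and not in the control. PF4, a platelet chemokine, was at 15.1 TPM in the scramble of the shM16 table alone. SLC2A3, a glucose transporter, stood at 36.4 TPM or more and CRABP2, a retinoic acid binder, at 15.5 TPM or more in both sheIF4E2 samples alone, and S100P at 12.2 TPM in their control alone. In all, 332 genes were listed in the control alone and 578 in every treated sample alone in the sgM16 table, 793 and 757 in the shM16 table, and 401 and 421 in the sheIF4E2 table.

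Nuclear TPM per mitochondrially encoded TPM was 4.78 in the input of the untreated control, 1.61 in the scramble of the shM16 table and 5.13 in that of the sheIF4E2 table. In footprints it was 16.5, 4.11 and 15.4, and it was 1.33 in the METTL16 knockdown. The footprint pair of the clones spread by a chi-square of 3.05 per degree of freedom, and that of sheIF4E2 by 1.6.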
